A study of Branchiostoma belcheri with 2 samples.

How the data were processed

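Gill RNA of the Chinese amphioxus *Branchiostoma belcheri*, an invertebrate chordate, was measured on 1-colour microarrays for microRNAs (miRNAs, short RNAs that bind messenger RNAs and lower their translation or stability). There was 1 control array and 1 LPS array. Per the labels, the LPS animals received 15 µl of lipopolysaccharide at 1 mg/ml in PBS into the body cavity, and control animals received the same volume of PBS. The LPS array is labelled as 12 h after injection, and the label of the control array gives no time. The number of animals behind each array is not given in the sources used here. Groups were taken from the agent named in the labels of each sample.

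Per the labels, total RNA was given a poly(A) tail and ligated to a Cy3-stained tag before hybridisation. Each scanner file listed 3968 spots. Of these, 3372 belonged to 1686 miRNA probes with 2 repeat spots each, and 596 were control spots, including 304 empty spots. The probes were designed for miRNAs of 11 species, with 93 for *B. belcheri* (prefix bbe) and 167 for *Branchiostoma floridae*, the Florida amphioxus (prefix bfl). These 260 are called amphioxus probes here, and the other 1426 came from 9 other animals, among them tunicates (cin, csa, odi), sea lamprey (pma), zebrafish (dre), a clawed frog (xtr), an acorn worm (sko) and a sea urchin (spu). Per the file headers, the spot value is the median pixel intensity of the Cy3 channel on a linear scale, with no background column. On the LPS array 16 spots lay above 65535 (highest 76957), whereas the control array stopped at 65535, and the sources used here do not say whether the LPS scan was rescaled, which would bear on differences of the brightest probes. The scanner, the extraction software and the miRNA database release are not given in the sources used here. The authors also deposited a value table with 1 processed intensity per probe and array. Its values tracked the spot intensities closely within each array (Spearman 0.985 on the control array and 0.978 on the LPS array, across detected probes). Among probes above 1000 in the scan, the spot intensity minus the empty-spot level was a median of 2.34 times the deposited value on the control array and 0.81 times on the LPS array. The medians of its columns were 6.88 and 3.42, its lowest value was 0.01, and the authors' background and scaling steps for this table are not given in the sources used here.

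Spot intensities were background-corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50, fitted on all spots), converted to log2, quantile-normalized between the arrays over the miRNA spots, and averaged over the 2 repeat spots of a probe, which is the main setting. A probe counted as detected when its mean intensity exceeded the 95th percentile of the empty spots of that array. A probe was counted as higher or lower on the LPS array when it was detected on at least 1 array, its normalized signal differed at least 2-fold, and the repeat spots of the arrays did not overlap. Each group had 1 array, so no test between groups was possible and no p-value is given. The SE beside a log2 difference covers the spread between repeat spots only, which is technical. For probes detected on 1 array only, a lower bound of the fold was computed against the higher of the probe's own value and the lowest normalized signal among detected probes of the dimmer array, and is written as "at least".

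Before the data were examined, 10 lists of miRNA families were fixed, along with a class of names numbered 1000 or higher, the threshold of 2-fold, the alternatives and the rule for named probes. A list's members are all detected probes of the named families, from every species on the array. The median of a list was placed among 10000 random lists of the same size matched on 10 classes of mean intensity, as a description of these 2 arrays. Members of a list are often close in sequence and can bind the same RNA, whereas random lists mix families. Extreme percentiles are therefore easier to reach for such a list than the random lists imply. Probes were named by rule: the 12 with the largest increase and the 12 with the largest decrease among counted probes detected on both arrays, up to 4 per direction with the largest lower bound among those detected on 1 array, the 5 brightest, and the members of each list with up to 6 detected (otherwise the 3 with the largest difference). Names outside this rule, including the account of the amphioxus probes and of whole families, were chosen after their values were seen. Families with at least 3 probes detected on both arrays and at least 2 species were summarised, 32 in all.

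The alternatives were normexp offsets of 16 and 200, no background correction, scaling to the array median over probes detected on both arrays, loess (span 0.4), no normalization between arrays, scaling on the perfect-match calibration spots, other detection filters, other thresholds, leaving out each repeat spot, and the deposited table (log2 after adding 50). Because the arrays' distributions differ in shape, median scaling left a median log2 difference of 0.77 over the probes it was computed on. Median scaling and scaling on the calibration spots add a fixed positive amount to each log2 difference found with no normalization. A probe above 0 with no normalization is thus above 0 in both by construction. These scalings are therefore not separate checks of its sign. Chosen after seeing the data were subtraction of the empty-spot median with a floor of 20, the amphioxus probes alone, 2 treatments of probes whose spots differed over 2-fold, and detection at the empty-spot mean plus 3 SD. The closest amphioxus target of a probe is the closest other amphioxus probe on the array. Differences from it in sequence were counted as substitutions, insertions and deletions (edits). Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

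The procedure was tested on simulated spots of this comparison (1686 probes, of which 200 were changed). It recovered 76.5% of probes raised 3-fold, 61.2% of those lowered 3-fold, 91.8% of those raised 6-fold and 100% of those lowered 6-fold, and it counted 3 of 1486 unchanged probes. The simulation used the median repeat-spot noise and the spread of empty spots, and holds no variation between animals or arrays. Both simulated arrays were built from the control intensities, with no loss of mismatch signal and no discordant LPS spots. The changed probes were all detected on both arrays and above 400 on the control array, and the unchanged ones include undetected probes, which cannot be counted. These rates therefore do not carry over to dim probes or to the noise of the LPS array. Of 200 random lists drawn from the 684 detected probes, 4.5% fell outside the central 95% of matched lists. These lists also mixed families, so the rate does not cover lists of probes close in sequence. Genome positions of the miRNAs are not given here, because the gene table at hand (assembly Haploidv18h27) lists no miRNA gene by name.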

Results

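The arrays asked which miRNAs of the amphioxus gill differ after injection of lipopolysaccharide (LPS), a lipid of the outer membrane of Gram-negative bacteria. Signal was compared between 1 control array (PBS) and 1 LPS array (12 h), so differences carry no replicate check. On the control array 648 of 1686 probes were detected (38.4%), and on the LPS array 339 (20.1%). Both arrays detected 303 probes, 345 were detected on the control array only, and 36 on the LPS array only. Empty spots had a median intensity of 107.3 (SD 10.6) on the control array and 99.8 (SD 30.5) on the LPS array. The repeat spots of detected probes had a pooled SD of 0.21 log2 units on the control array and 0.721 on the LPS array. Values after ± below are the SE over 2 repeat spots per array, a technical error only, and log2 differences are LPS minus control in normalized intensity.

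Among the amphioxus probes, miR-4866-3p showed the largest increase on the LPS array, and miR-10c the largest decrease. The *B. belcheri* probe for miR-4866-3p (GCUUAGCAGUGCAAGUGUGAC) was 5.31-fold higher (log2 difference 2.41 ± 0.36), and the *B. floridae* probe 4.02-fold higher (2.01 ± 0.29). The probe bfl-miR-10c, of a family that lies in the Hox clusters of animals, was 8.18-fold lower (-3.03 ± 0.51). In all, 34 amphioxus probes were higher and 8 were lower by at least 2-fold, out of 204 detected. The *B. belcheri* probes gave 10 higher and 7 lower of 78, and the *B. floridae* probes 24 higher and 1 lower of 126. The pooled counts were 105 and 7 with median scaling and 45 and 11 with scaling on the calibration spots, but 5 and 12 with loess and 4 and 29 with no normalization. The other species' probes gave 38 higher and 64 lower out of 480 detected, against 230 and 47 with median scaling and 132 and 52 with scaling on the calibration spots. With loess they gave 17 and 90, and with no normalization 21 and 99.

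Higher amphioxus probes included members of several conserved families. bfl-miR-34b-5p was 3.12-fold higher (1.64 ± 0.18), and miR-34 is known in vertebrates as a target of p53 and for its abundance in ciliated cells. bfl-miR-29a-3p (1.24 ± 0.06) and bfl-miR-29a-5p (1.52 ± 0.06) were both higher, as were bfl-miR-125a-3p (2.82-fold, SE 0.09 log2 units) and bfl-miR-31-5p (1.49 ± 0.32). The probes bfl-miR-71-5p (1.09 ± 0.08) and bfl-miR-71-3p (1.22 ± 0.04), of a family missing from vertebrates, were higher in this normalization, but both were below 0 with no normalization between the arrays (-0.08 and -0.11). Lower amphioxus probes besides miR-10c were bbe-miR-2063-3p (-2.44 ± 0.11), bbe-miR-92d-3p (-2.26 ± 0.49), bbe-miR-190-3p (-2.24 ± 0.08), bbe-miR-34a-5p (-1.69 ± 0.19) and bbe-miR-4877-3p (-1.61 ± 0.27). bbe-miR-33-5p was not detected on the LPS array and was at least 2.77-fold lower. The remaining lower probe was bbe-miR-135a-5p (-2.74 ± 2.24), whose repeat spots on the LPS array differed by 4.47 log2 units and which was at 0.19 in the deposited table. Of the 34 higher amphioxus probes, 20 stayed above 0 in each of 5 other scalings, and the other 14 fell below 0 with no normalization. For a probe above 0 with no normalization, the sign with median scaling and calibration spots follows by construction. A kept sign can still mean a value near 0. With no normalization bfl-miR-34b-5p was at 0.19, bfl-miR-29a-5p at 0.15, bfl-miR-125a-3p at 0.15 and bfl-miR-31-5p at 0.12, while bfl-miR-29a-3p was at 1.08. The lower amphioxus probes stayed below 0 in each of those scalings in 7 of 8 cases, bbe-miR-135a-5p being the exception.

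Over all probes, 72 were higher and 72 lower, of which 13 and 30 were detected on 1 array only. The split moved with the scaling: 335 higher and 54 lower with median scaling, 177 and 63 with scaling on the calibration spots, 22 and 102 with loess, and 25 and 128 with no normalization. The median log2 difference of the 684 detected probes was -0.10 in the main setting. It was 0.99, 0.70, -0.39 and -0.18 in those other scalings, in the same order. In all 5 other scalings 53 of the 72 higher and 65 of the 72 lower kept their sign. Median scaling, calibration spots and no normalization differ only by a constant, so these are not 5 separate checks. Of the 144 counted probes, 115 were still counted with median scaling, 103 with scaling on the calibration spots, 94 with loess and 92 with no normalization.

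**Figure D1:**
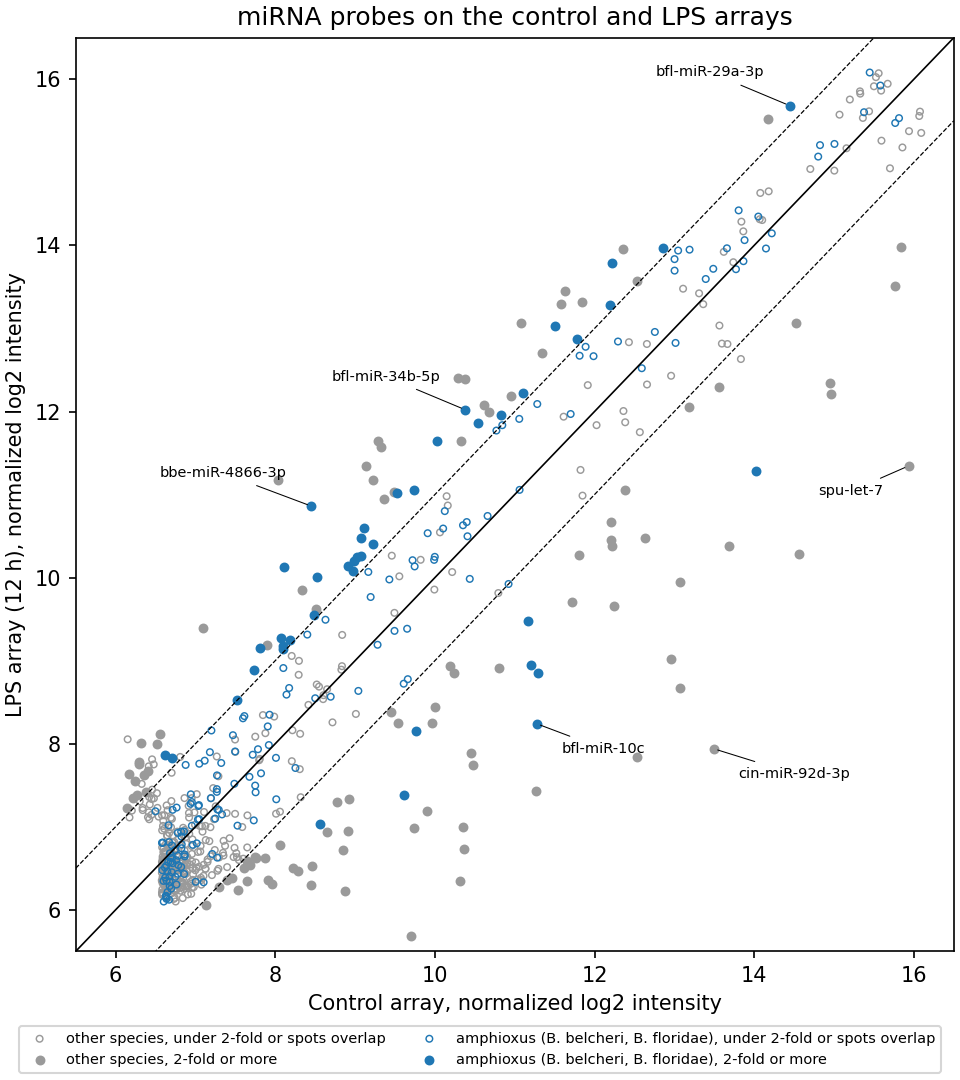
Normalized log2 intensity of each of the 684 detected probes on the control array (horizontal axis) and the LPS array (vertical axis). Each point is the mean of 2 repeat spots, filled points differ at least 2-fold with separate repeat spots, blue points are amphioxus probes and grey points are probes of other species. The solid line marks equal signal and the dashed lines a 2-fold difference. Of the blue filled points, 34 lie above the solid line and 8 below it. spu-let-7 rests on repeat spots that differ by 7.92 log2 units on the LPS array.

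The probes with the largest increases of any species were led by the sea squirt probe cin-miR-4019-5p (8.82-fold, 3.14 ± 0.38) and included cin-miR-4127-5p (2.29 ± 0.06), cin-miR-4020a-5p (2.01 ± 0.11) and odi-miR-1474 (1.94 ± 0.17). Their sequences are 8, 7, 7 and 6 edits from the closest amphioxus target, so which amphioxus RNA gave their signal is not known. The rest of these 12 were the miR-4866-3p probes, xtr-miR-31a, csa-miR-31, sko-miR-9 (2.24 ± 0.68), sko-miR-190 (2.11 ± 0.28), sko-miR-34-5p (1.98 ± 0.15) and cin-let-7d-5p. All 12 stayed above 0 in each of the 5 other scalings, where median scaling and calibration spots follow by construction from no normalization. The largest decrease was that of cin-miR-92d-3p, from an intensity of 14697 to 203.5 (47.0-fold, -5.55 ± 0.23). Its sequence is 2 edits from the closest amphioxus target. Probes of let-7, a regulator of developmental timing, and of the related miR-98 took 5 of the 12 places among the largest decreases. Among probes detected on the control array only, xtr-miR-10b was at least 9.67-fold lower, dre-miR-10d-5p at least 9.60-fold, cin-let-7c at least 9.36-fold and pma-miR-29d-3p at least 6.55-fold lower on the LPS array. The largest bounds in the other direction were pma-miR-26a-1-3p (at least 2.91-fold), cin-miR-4011b-3p (2.71-fold), pma-miR-144-3p (2.67-fold) and cin-miR-4147-3p (2.30-fold). The repeat spots of these 4 on the LPS array lay between 1.28 and 2.74 log2 units apart, and in the deposited table pma-miR-144-3p was at 0.11, pma-miR-26a-1-3p at 0.68 and cin-miR-4147-3p at 0.70, all under 2-fold.

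The list of let-7, miR-100 and miR-125, which share a cluster in many animals, stood lowest against random lists. Of its 44 detected probes, 18 were lower, 4 were higher and 22 did not pass, with a median of -0.65 (percentile 0 of random lists, to 1 decimal). Many of these probes are close in sequence and can bind the same RNA, so they are not 44 separate measurements. The random lists do not share this. Relative to all detected probes the median was -0.55, and between -0.49 and -0.57 in the 5 other scalings, although the list's own median was above 0 with median scaling (0.42) and calibration spots (0.13). Median scaling, calibration spots and no normalization differ only by a constant for all probes, so their relative medians (-0.57) are equal by construction. Examples were dre-let-7e (-4.69 ± 0.48), xtr-miR-98 (-4.40 ± 0.12), dre-let-7g (-4.28 ± 0.27) and pma-let-7b-5p (-3.30 ± 0.68). spu-let-7 (-4.59 ± 3.96) rested on 1 dim repeat spot on the LPS array and was at 0.66 in the deposited table. The zebrafish let-7a probe (UGAGGUAGUAGGUUGUAUAGUU) did not pass at -0.56 ± 0.04 and was above 0 with median scaling (0.80), calibration spots (0.51) and in the deposited table (0.88). Probes 1 edit from it gave 4 of 6 lower, spu-let-7 among them, and those 2 edits from it gave 7 of 8 lower, the exception being cin-let-7d-5p, which was higher (1.82 ± 0.11). At 3 or more edits 5 of 11 were lower and 1 was higher, with a median of -0.88 against -2.05 at 1 edit and -1.94 at 2 edits. In that class all but cin-let-7e were below the LPS detection threshold (143.5), and most lay between 141 and 383 on the control array. How far they could fall was thus limited, and their median cannot be compared with the others. The 8 amphioxus probes of the list had a median of 0.68, with 2 higher and 0 lower, but 7 of them were closer to the reverse complement of a let-7, miR-100 or miR-125 probe than to the probe itself. Of these, bfl-let-7b and bfl-miR-125b are exact reverse complements (0 edits). The rest are named as 3p arms and lie 7 to 9 edits from the reverse complement. The remaining amphioxus probe, bfl-miR-100-5p, stood at -0.28 ± 0.04 but was above 0 with median scaling (1.20), calibration spots (0.91), no normalization (0.03) and in the deposited table (1.27). On the maker's calibration spots, signal on mismatched probes relative to their perfectly matched partners was lower on the LPS array in 23 of 23 usable pairs (median 10.3% on the control array and 1.01% on the LPS array). In usable pairs the mismatched spots lay above the detection threshold of the control array (121.9), with no such demand on the LPS array. That choice favours pairs lower on the LPS array. Among the pairs left out, Ctr02-3M05 was not lower.

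**Figure D2:**
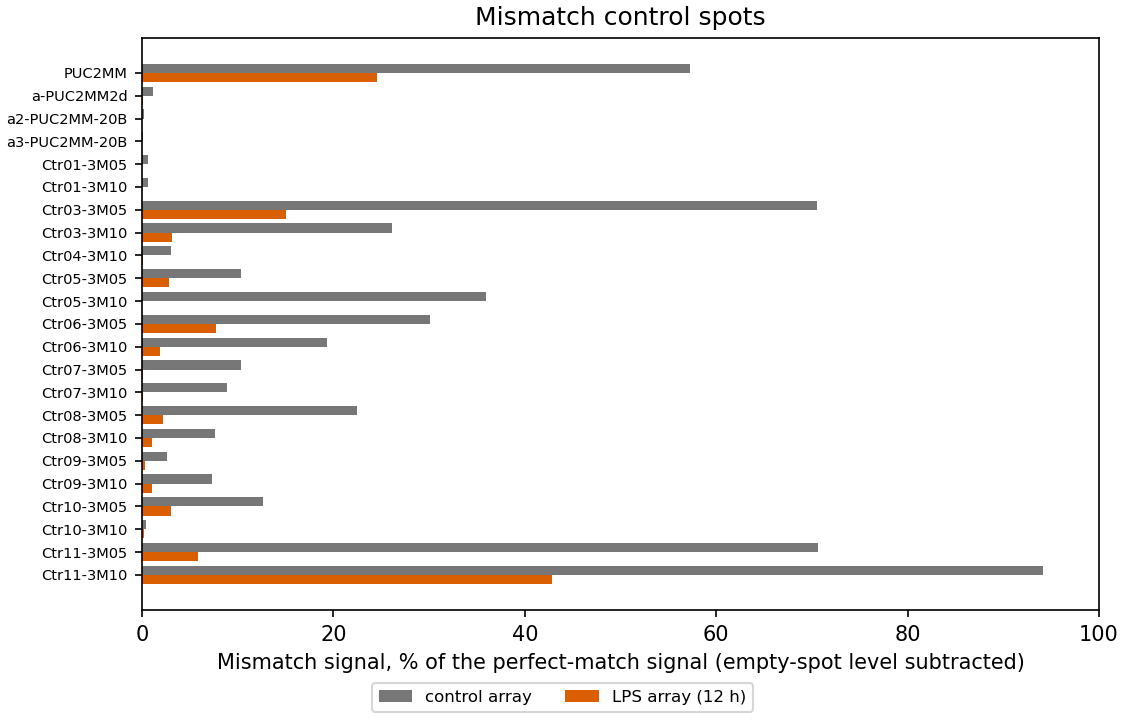
Signal of mismatched calibration spots as a percentage of their perfectly matched partners (horizontal axis), after subtraction of the empty-spot median (values below 0 on the LPS array set to 0), for each of the 23 usable pairs (vertical axis). Grey bars are the control array and orange bars the LPS array, each from the median of at least 4 spots. The orange bar is the shorter in every pair, with medians of 10.3% and 1.01%. Usable pairs have mismatched spots above the detection threshold of the control array, which favours pairs lower on the LPS array.

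Hox-cluster miRNAs (the miR-10 and miR-196 families among the detected) gave 6 lower and 1 higher of 13 detected probes, with a median of -0.39 (percentile 10.1). The higher member was bfl-miR-10b (1.32 ± 0.33), which was at 0.01 with no normalization. For the miR-17-92 and miR-25 family, 11 of 41 detected probes were lower and 1 was higher, with a median of 0.01 (percentile 42.1). Lower members included dre-miR-25 (-3.83 ± 0.17), spu-miR-92d (at least 6.11-fold lower) and cin-miR-92c-3p (-2.76 ± 2.51). The last rested on repeat spots 5.03 log2 units apart on the LPS array and was at 0.87 in the deposited table. The brightest probes of the array included xtr-miR-92b (0.51 ± 0.05), sko-miR-92b (0.50 ± 0.14) and pma-miR-92a (0.27 ± 0.04), none of which passed the 2-fold threshold. All 3 passed it with median scaling, scaling on calibration spots and in the deposited table (1.49 to 2.21), and the LPS intensity of xtr-miR-92b (74432) lay above the highest spot of the control array. dre-miR-125c (-0.47 ± 0.05) and dre-miR-125b (-0.51 ± 0.04, with 1 control spot saturated) did not pass either. These 2 miR-125 probes were above 0 with median scaling, scaling on calibration spots and in the deposited table.

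Vertebrate inflammation miRNAs gave 8 higher and 6 lower of 44 detected probes, with a median of 0.01 (percentile 39.8). The higher members were 4 miR-29 probes, 3 miR-210 probes and bfl-miR-125a-3p. miR-210 is known in vertebrates as a hypoxia-responsive miRNA, and bfl-miR-210-3p (1.33 ± 0.09), pma-miR-210 (1.31 ± 0.08) and dre-miR-210-3p (1.23 ± 0.07) all turned below 0 with no normalization (-0.18, -0.13 and -0.18). The lower members included pma-miR-22b-3p (-3.94 ± 0.86) and pma-miR-22a-3p (-3.12 ± 0.40), each 2 edits from the closest amphioxus target, while bbe-miR-22-3p stood at 0.30 ± 0.04. miR-146 and miR-155, which LPS induces in mammalian macrophages, had 10 probes, all for other species. Detected were 1 of 6 for miR-146 (xtr-miR-146a, on the LPS array only) and 1 of 4 for miR-155 (dre-miR-155, on the control array only), neither past the threshold. The 13 detected amphioxus probes of this list had a median of 0.87, with 5 higher and 0 lower. All 204 detected amphioxus probes had a median of 0.18, with 34 higher and 8 lower. With no normalization, bfl-miR-210-3p (-0.18) and bfl-miR-29b-5p (-0.02) of these 5 were below 0. There bfl-miR-29a-5p and bfl-miR-125a-3p were each at 0.15, and bfl-miR-29a-3p was at 1.08.

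Epithelial and ciliated-cell miRNAs had 11 higher and 6 lower of 50 detected probes, with a median of -0.07 (percentile 42.7). miR-31 probes accounted for 5 of the higher ones, xtr-miR-31a (2.36 ± 0.05) and csa-miR-31 (2.22 ± 0.15) among them, and miR-34 probes for another 5. The miR-200 family, known for its epithelial expression in vertebrates, gave 3 lower and 1 higher of 14 detected. dre-miR-200a was 4.01-fold lower (SE 0.14 log2 units), and bbe-miR-200a-3p, a probe for the opposite arm, stood at 1.35 ± 0.23. The closest amphioxus target of dre-miR-200a, bbe-miR-200c-3p at 2 edits, stood at -0.06 ± 0.02 and at 1.02 in the deposited table.

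The lists for other tissues included muscle, neural, gut, blood and gonad miRNAs. Muscle miRNAs gave 3 lower and 0 higher of 22 detected (median -0.06, percentile 41.4). The lower ones were cin-miR-1-3p, pma-miR-1a-3p and pma-miR-1b, all undetected on the LPS array, with bounds of at least 2.95-fold, 1.43-fold and 1.15-fold. pma-miR-1b was at 0.13 with median scaling. Neural and sensory miRNAs gave 3 higher and 3 lower of 41 (median -0.05, percentile 65). bfl-miR-137 (1.40 ± 0.20) was higher, but at 0.05 with no normalization. xtr-miR-9-5p was lower (-1.71 ± 0.18) whereas sko-miR-9, 1 edit from it, was higher (above), and dre-miR-9-5p, also 1 edit from it, stood at -0.15 ± 0.11. Endoderm and gut miRNAs gave 2 lower and 0 higher of 26 (median 0.03, percentile 80.7), namely dre-miR-216b (at least 6.28-fold lower) and cin-miR-217 (-2.74 ± 0.28). bfl-miR-216-3p stood at 0.72 ± 0.19 and did not pass. Of 18 blood and endothelial probes 2 were detected, pma-miR-144-3p (above) and dre-miR-142b-5p (0.08 ± 0.17, not detected on the LPS array). Of 17 gonad probes 4 were detected and none passed, dre-miR-430a (-0.70 ± 0.10), dre-miR-202-3p (-0.23 ± 0.08), dre-miR-430b (-0.05 ± 0.11) and xtr-miR-202-3p (0.08 ± 0.05), with a median of -0.14 (percentile 86.1), and dre-miR-430b was the only gonad probe detected on both arrays. Names numbered 1000 or higher, mostly miRNAs described in few lineages, gave 34 higher and 9 lower of 294 (median -0.08, percentile 99.8), a median 0.02 above that of all detected probes.

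**Figure D3:**
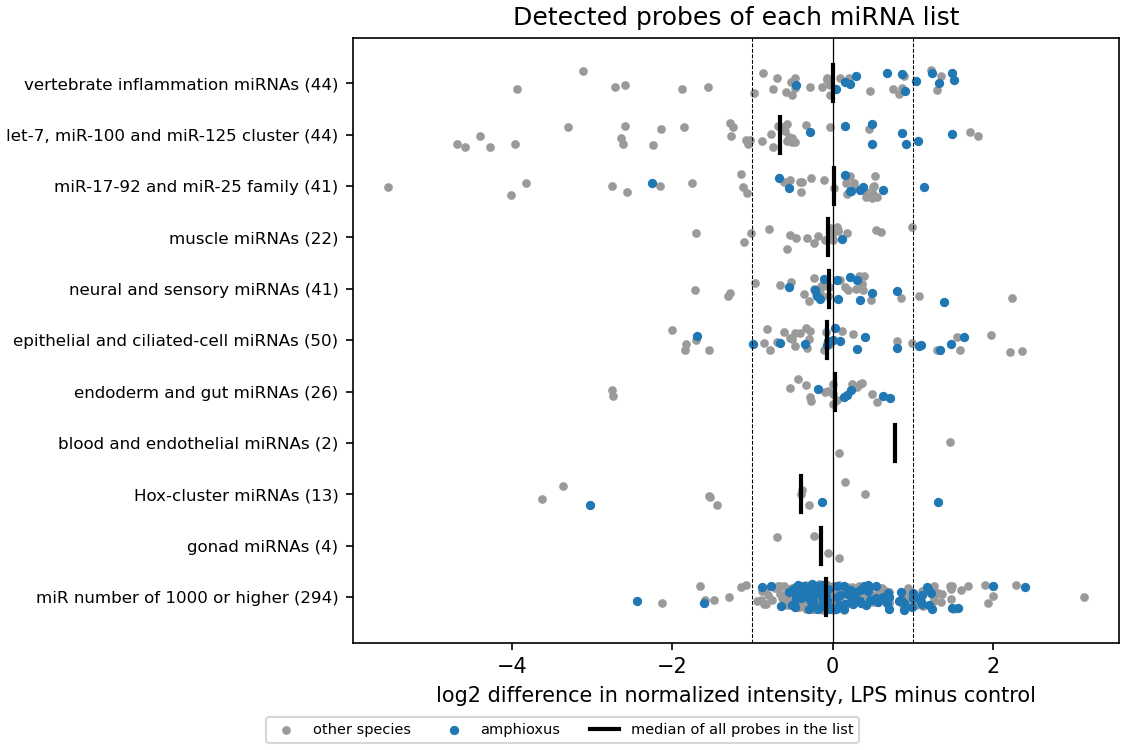
Log2 difference in normalized intensity, LPS minus control (horizontal axis), of each detected probe of the lists fixed beforehand (vertical axis, with the number of detected probes in brackets). Blue points are amphioxus probes, grey points are probes of other species, black bars are list medians and dashed lines mark a 2-fold difference. The median of the list of let-7, miR-100 and miR-125 lies at -0.65. Its 8 amphioxus probes, 7 of them closer to the reverse complement of such a probe, have a median of 0.68.

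The log2 differences in the deposited table correlated with those from the spot intensities at a Pearson r of 0.877 across the 303 probes detected on both arrays, which are not independent replicates. Of the 144 counted probes, 141 had the same sign in it. Treatment and array could not be separated with 1 array per group, and perfectly matched calibration spots were at a median of 0.734 of their control-array signal on the LPS array (range 0.165 to 1.01 over 15 types). On the LPS array 65 detected probes had repeat spots over 2-fold apart, against 13 on the control array, and 21 of the 144 counted probes had such spots on either array.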

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

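The tests on calibration spots, on other treatments of discordant repeat spots, on the amphioxus probes without normalization and on miR-31 were chosen only after their values were seen. Those on edit distance and on the gap between repeat spots were fixed before their own values were seen. By then let-7 and miR-98 values were known, and the gap test was narrowed to other species' probes later. The description of the pattern in other species' probes was reworded after its counts were known, with the numeric bounds of its tests left as they were.

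The array also carries 6 types of control spots for zebrafish 5S ribosomal RNA, 4 spots each, which no comparison above uses. Signal was above the detection threshold for 4 types on the control array and 3 on the LPS array, and dre-5S-b5 and dre-5S-b6 were below it on both. Median intensity of dre-5S-b1 was 3156 on the control array and 1406 on the LPS array. It was 13180 and 2088 for dre-5S-b3, and 3642 and 986.8 for dre-5S-b4. dre-5S-b2 gave 641.2 on the control array and was not above the detection threshold on the LPS array. The LPS file also held a stray value of 5410 in an otherwise empty density column, beside a spot whose own median was 2459.

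Probes for other species' miRNAs were more often lower (64) than higher (38) on the LPS array, a split that turned round with median scaling (47 lower, 230 higher) and scaling on calibration spots (52 and 132). It widened with loess (90 and 17) and with no normalization (99 and 21). Damaged or unevenly hybridised spots stay open as a cause. The counted probes of other species had a median gap of 0.437 log2 units between repeat spots (95% bootstrap interval 0.32 to 0.50), against 0.231 for those not counted. Over all 144 counted probes the gap was 0.376, under the 0.5 set beforehand, but above the 0.253 of detected probes not counted, so that bound was too loose to decide. No block among 4 equal blocks of rows held more than 30.4% of their spots. With discordant repeat spots left out the split was 58 lower and 25 higher, while with the brighter of them it was 69 and 70. A candidate explanation is stricter hybridisation or washing on the LPS array. Mismatched calibration spots lost signal relative to their partners in 14 of 14 usable control families. These were kept for mismatch signal on the control array, a choice that favours a loss. The edit-distance test, fixed before its own values but after those of let-7 and miR-98 were seen, left this open. Probes 1 to 4 edits from the closest amphioxus target had a median -0.232 relative to amphioxus probes (95% bootstrap interval -0.58 to -0.02), between the bounds of -0.5 and -0.2 set for and against it. let-7 and miR-98 were left out, but their 29 detected probes of other species all lie at 5 or more edits. Medians by class did not fall steadily with edits, at 0.01 for 1 to 2 edits, -0.23 for 3 to 4 and -0.19 for 5 or more, while the share counted as lower was 20.3%, 28.3% and 5.8%, against 4% of amphioxus probes. This order cannot decide, because edits were counted only to amphioxus probes on the array. The class of 5 or more thus also holds probes such as dre-miR-125b (7 edits), whose amphioxus namesake bfl-miR-125b is its reverse complement. Brightness also differed between the classes, and dim probes have little room to fall. Above 400 on the control array lay 60 of 69 probes at 1 to 2 edits, but 46 of 329 at 5 or more. Over probes above 400, a choice that favours probes lower on the LPS array, the shares lower were 21.7%, 54.2% and 21.7%. For amphioxus probes above 400 the share was 8.6%. For 3 to 4 edits the median was -1.29 over probes above 400 on the control array, and 0.25 over probes detected on both arrays. The treatment itself also stays open and untested, with 1 array per group.

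Amphioxus probes showed the opposite split, 34 higher and 8 lower (10 and 7 for *B. belcheri* probes, 24 and 1 for *B. floridae* probes), which turned round with loess (5 and 12) and with no normalization (4 and 29). Whether matching the distributions of the arrays accounts for it stays open. With no normalization the median of the 204 detected amphioxus probes was -0.151, against 0.18 in the main setting, but that of all detected probes was also below 0 (-0.18). The excess of amphioxus probes over other species' probes was 0.40 log2 units in the main setting, 0.04 with no normalization, median scaling or calibration spots, 0.35 with loess and 0.74 in the deposited table. The equal values of 0.04 follow by construction, since those scalings differ only by a constant for all probes. An effect of LPS on part of these miRNAs stays open, untested.

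All 6 miR-31 probes detected on both arrays were above 0 on the LPS array, a family singled out among 32 after its values were seen. These 6 are close in sequence and are not separate observations. Other families also had every such probe above 0, among them miR-375 (7 probes), miR-71 (4) and miR-2071 (4). None of the 32 families kept 1 sign for all its probes in all 10 settings compared. The 3 miR-31 probes detected on the control array only were below 0 and not counted (pma-miR-31 at -0.70 ± 0.13, odi-miR-31 at -0.47 ± 0.14, bbe-miR-31-3p at -0.34 ± 0.13). With no normalization the median of the 6 probes detected on both arrays was 0.184, with 5 of 6 above 0 and spu-miR-31 at -0.54. Matching of the distributions could therefore account for part of the difference, and this cannot be told apart from a response to LPS, with 1 array per group. The family median stayed above 0 with loess (0.91). Its values with median scaling (1.35) and scaling on calibration spots (1.07) add a fixed amount to that with no normalization. They are above 0 by construction.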

How the results depend on the processing

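The alternatives of amphioxus probes alone, empty-spot subtraction, discordant spots (brighter or left out) and detection at 3 SD were chosen after seeing the data, and where a value moved the cause was not tested unless stated. The total of 144 counted probes became 95 with an offset of 200, 389 with median scaling, 240 with scaling on calibration spots, 235 at 1.5-fold, 63 at 3-fold and 42 over amphioxus probes, the last 3 by construction. The 72 higher became 44 with an offset of 200, 335 with median scaling, 22 with loess, 25 with no normalization, 177 with calibration spots, 111 in the deposited table, 109 with the brighter of discordant spots, 34 over amphioxus probes, 110 at 1.5-fold and 18 at 3-fold. The 72 lower became 113 with empty-spot subtraction, 128 with no normalization, 42 over probes detected on both arrays, 8 over amphioxus probes, 125 at 1.5-fold and 45 at 3-fold. Other settings kept these counts within 1.5 times.

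List medians are relative to all detected probes. Median scaling, calibration spots and no normalization, which differ only by a constant, therefore give the same value for each list. Over amphioxus probes alone, the list of let-7, miR-100 and miR-125 turned from -0.55 to 0.50 (7 of its 8 amphioxus probes are closer to a reverse complement). The inflammation list went from 0.11 to 0.68, the neural list from 0.05 to -0.12, and names numbered 1000 or higher from 0.02 to -0.068, also over amphioxus probes alone. Over probes detected on both arrays, the neural list was at -0.081, the endoderm list at -0.036 and names numbered 1000 or higher at 0.24. The endoderm list moved from 0.14 to -0.18 with median scaling, calibration spots or no normalization, and names numbered 1000 or higher to 0.11. In the deposited table the endoderm list was at 0.52 and the miR-17-92 and miR-25 family at 0.69 (0.11 in the main setting). The inflammation list was also at 0.52 there (0.11 in the main setting), inside its 95% bootstrap interval. The Hox list went from -0.29 to -1.05 with median scaling, calibration spots or no normalization, inside its wide 95% bootstrap interval. Lists not named here stayed inside theirs. The blood list, with 2 probes and no interval, went from 0.88 to 0.19 in the deposited table.

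Detected probes fell from 648 to 380 on the control array and from 339 to 221 on the LPS array at the empty-spot mean plus 5 SD. Of 42 counted probes named by rule, 4 changed sign: in the deposited table spu-let-7 (0.66), cin-miR-92c-3p (0.87) and bbe-miR-135a-5p (0.19), each with discordant LPS spots, and with median scaling pma-miR-1b (0.13). Of the other values of the 53 named probes, 402 stayed within the repeat-spot SD and 230 moved beyond it. Dim probes near the empty-spot level limit what a fold can show. Not run were local background subtraction, since no background column was read, the median of 2 spots, which equals their mean, and leaving out replicates. No paired analysis was possible because each group has 1 array.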

Other observations

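The families named here were chosen after their values were seen. Members of the same family differed from each other. In miR-34, bfl-miR-34b-5p (1.64 ± 0.18), bbe-miR-34b-3p (1.10 ± 0.07) and bfl-miR-34d (1.08 ± 0.25) were higher on the LPS array and bbe-miR-34a-5p (UGGCAGUGUGGAUAGCUGGCCGU) was lower (-1.69 ± 0.19), while bfl-miR-34a was below 0 (SE 0.12 log2 units), just short of the threshold in normalized signal. These 4 counted probes kept their signs in all 5 other scalings. With no normalization, however, the higher ones were near 0, at 0.19, 0.18 and 0.01 in the order given. In miR-190, bfl-miR-190 was higher (1.13 ± 0.09) and bbe-miR-190-3p, the opposite arm, was lower (-2.24 ± 0.08), with bfl-miR-190 at -0.27 with no normalization. In miR-29, bfl-miR-29a-3p was higher (1.24 ± 0.06), while bbe-miR-29b-3p stood at -0.45 ± 0.20 and xtr-miR-29b was lower (-1.55 ± 0.47). In miR-33, pma-miR-33a was lower (-1.39 ± 0.08), and the other probes detected on both arrays did not pass, with bfl-miR-33 at -0.88 ± 0.23 and bbe-miR-33-3p at -0.09 ± 0.11. bbe-miR-33-2-3p differed by less than its SE of 0.41 log2 units and was at 0.41 in the deposited table.

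Probes for miRNAs described in amphioxus and few other animals also differed within families. The miR-4866-3p probes were higher on the LPS array in every scaling, between 1.02 and 2.60 on the log2 scale, whereas bfl-miR-4866-5p (48837 on the LPS array, 49730 on the control array) stood at -0.29 ± 0.14, with the sign positive with median scaling (1.15), scaling on calibration spots (0.86) and in the deposited table (1.23). Of 4 miR-2071 probes, bbe-miR-2071-3p (1.19 ± 0.01) and bfl-miR-2071-5p (1.18 ± 0.08), 1 edit apart in sequence, were higher, and both were below 0 with no normalization (-0.18 and -0.22). The other miR-2071 probes (0.89 and 0.69) did not pass, but were above them in the deposited table (1.63 and 1.42 against 0.99 and 0.95). bfl-miR-4874-3p (1.57 ± 0.06) and bfl-miR-705 (1.62 ± 0.08) were higher here and above 0 in every scaling, at 0.54 and 0.24 with no normalization.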
